A study of Mus musculus with 8 samples.

How the data were processed

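Nascent RNA of mouse bone marrow-derived macrophages was measured by GRO-seq at 0, 20, 60 and 180 min of LPS, with 2 biological replicates per time point, per the labels. The deposited table gave 1 FPKM value per gene and library for 22753 genes, with gene coordinates on mm9. Per the labels, the authors named CASAVA 1.7, Bowtie2 2.0.5 and HOMER 4.6 and 4.7, without the role or order of each. Strand handling, exon or whole-gene counting, treatment of duplicate reads and the reads that made up the total behind each FPKM are not given in the sources used here. In 99.3% of genes the listed length equalled end minus start, so lengths were whole gene spans. Whether starts count from 0 or from 1 is not given. Because strand handling is not given, values of overlapping and antisense genes are uncertain. The file listed 337 genes with more than 1 copy, of which 7 were among those tested, and reads shared between copies were not resolved. The table also held 8 columns of another treatment, which were not used here.

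Depth was recovered from the step size of the deposited FPKM in genes of up to 4000 bases. It came to 44.4 to 61.2 M reads for replicate 1 and 7.96 to 11.1 M reads for replicate 2. At these depths, 99.9 to 100% of the values used were whole reads within 0.1 read, against 20% by chance. The labels state over 50 M reads per library, which the recovered depth of 4 libraries of replicate 2 and 2 of replicate 1 did not reach. The method was tested on simulated data with 3 depths and returned each with an error of 0%.

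Groups came from the time and replicate number in the labels. Genes with a mean of at least 0.5 FPKM over the 8 libraries were kept, 8343 in number. The values used were log2(FPKM + 0.1), with the deposited FPKM scaled no further. Limma 3.58.1 in R 4.3.3 fitted the 4 groups in 1 model, with a variance trend and moderated two-sided tests. Benjamini-Hochberg correction was made within each comparison, and genes were called at an adjusted p under 0.05. Comparisons were 20, 60 and 180 min with 0 min, 60 with 20 min and 180 with 60 min, and an F-test covered the 3 comparisons with 0 min. This fit, without the replicate number, is the unpaired fit, and the same fit with the replicate number as a block is the paired fit. Both fits, the gene lists and the naming rule were fixed before the data were examined. A rule fixed with them took the replicate numbers to pair libraries if replicate 1 minus replicate 2 correlated above 0.1 between all 6 pairs of groups. The correlations were 0.59 to 0.88, so by this rule the replicate numbers paired the libraries. The unpaired fit had been fixed as the main one. The SE, the camera results and the fits with a library left out are unpaired, so they count the replicate difference as spread.

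The 25 gene lists held 470 members, of which 469 were in the file and 353 were tested, and 19 lists had at least 3 tested members. The other 6 were markers of T and NK cells, B cells, dendritic cells, mast cells, erythroid cells and stroma. Camera compared each list with all other genes at a preset correlation of 0.01, corrected over lists within a comparison. Alternatives were camera with the correlation estimated per list and fry, which tests a list without comparing it with other genes. Members were also corrected over each list alone.

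For each comparison with 0 min, the named genes were the 8 called genes with the largest change each way whose groups did not overlap and whose higher mean was at least 2 FPKM. For the other 2 comparisons 4 were taken each way. For each list, up to 4 called members with the largest change and up to 2 not called with the highest FPKM were taken. Tnf, Il1b, Il6, Nfkbia, Fos, Ccl4, Cxcl10, Ifit1, Ifnb1 and Actb were always included. Predicted genes, clone names and small RNAs were passed over. The same rule was applied to the paired fit after the data had been seen. Malat1 was named after its values were seen.

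Alternatives covered pseudocounts of 0.01 and 1, no filter, a filter of 1 FPKM, median-ratio scaling, quantile normalization, no variance trend, a robust trend, only the compared groups in the fit, and each library left out in turn. Keeping each listed entry as its own feature gave the same values, since symbols were unique. Voom on read numbers recovered from FPKM, length and depth, and median-ratio scaling together with the block, were added after the data had been seen, as were overlaps of calls with a different 0 min library in each comparison.

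The fits were tested on simulated data with 25 genes changed at each size between 180 and 0 min. The simulated libraries had the same replicate difference at every time and the residual spread of the paired fit, a setting that favours that fit. Far fewer genes were changed than were called in the data at 180 min, so the rates need not hold there. The unpaired fit called 0% of genes changed by 1 or -1 on the log2 scale, 28% and 20% at 2 and -2, 80% and 88% at 4 and -4, and 100% and 84% at 6 and -6, with 0 false calls. The paired fit called 64% and 52% at 1 and -1 and 96% to 100% at larger sizes, with 7 false calls. Camera called the changed list and 0 of 100 random lists. The simulated residual spread was drawn independently for each gene, so this did not test the preset correlation on lists whose members vary together.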

Results

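Nascent RNA was measured by global run-on sequencing (GRO-seq), which reads RNA made by polymerases engaged at the moment of harvest, in macrophages grown from mouse bone marrow. The cells received lipopolysaccharide (LPS), the cell wall component of gram-negative bacteria that is sensed through Tlr4, at 100 ng/ml. They were sampled at 0, 20, 60 and 180 min. Each of the 4 time points had 2 biological replicates (n = 2 in every group), giving 8 libraries. The depth recovered from the deposited values was 61.2, 56.8, 48.8 and 44.4 M reads for replicate 1 at 0, 20, 60 and 180 min. For replicate 2 it was 9.17, 9.14, 11.1 and 7.96 M reads. In a gene of median length, 1 read stood for 0.00109 to 0.00150 FPKM (fragments per kilobase of gene, scaled to the library total) in replicate 1 and for 0.00597 to 0.00835 FPKM in replicate 2. Of 22753 genes listed, 8343 passed the filter on low values. Values are mean FPKM ± SD, and changes are differences of log2(FPKM + 0.1) ± SE from limma, with adjusted p after Benjamini-Hochberg correction. The added 0.1 understates changes of genes with low values. The replicate number was left out of the unpaired fit and entered as a block in the paired fit.

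Replicates of the same time point had Pearson correlations across genes of 0.819, 0.874, 0.834 and 0.910 at 0, 20, 60 and 180 min. Libraries of the same replicate number correlated at 0.892 and 0.909 between 0 and 20 min in replicates 1 and 2. Between 20 and 60 min these were 0.825 and 0.798, and between 60 and 180 min 0.842 and 0.745. The first principal component held 57.1% of the variance and ordered the groups by time within each replicate number. The second held 19.8% and parted replicate 1 from replicate 2 at every time point. Malat1, a long noncoding RNA of the nucleus, was listed at 83.8 FPKM in replicate 1 and 1321 FPKM in replicate 2 at 0 min.

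**Figure D1:**
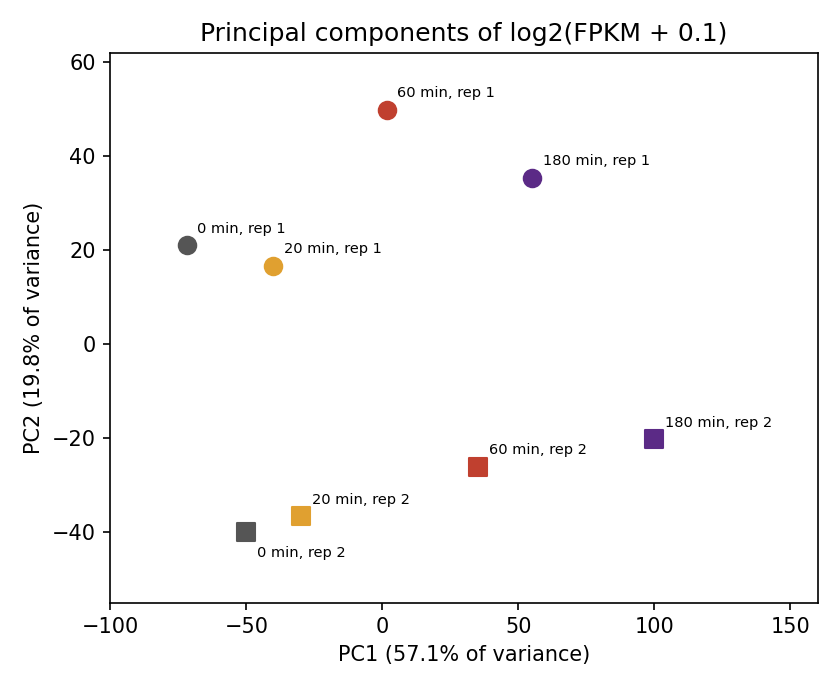
Principal components of log2(FPKM + 0.1) for the 8343 genes tested, with component 1 (57.1% of the variance) on the horizontal axis and component 2 (19.8%) on the vertical axis, both in log2 units. Each point is 1 library, and replicates 1 and 2 of every time point lie apart along component 2.

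Over the whole time course, the limma F-test called 2054 of 8343 genes, and 5516 in the paired fit. Of the 2054, the highest group mean was at 0 min for 1035 genes, at 20 min for 164, at 60 min for 329 and at 180 min for 526. After median-ratio scaling 1873 were called. By the deposited means, left unscaled, their highest mean was at these times for 704, 136, 375 and 658. The count was 1080 without 0 min replicate 1, 1047 without 0 min replicate 2, 1264 and 1160 without 20 min replicates 1 and 2, and 997 without 180 min replicate 2. Several time courses were visible among genes chosen in advance. Fos, an immediate early transcription factor, stood at 40.4 ± 8.02, 146 ± 7.95, 11.2 ± 0.00283 and 3.68 ± 1.10 FPKM at 0, 20, 60 and 180 min. Tnf, a cytokine, stood at 41.5 ± 15.1, 443 ± 10.9, 822 ± 288 and 681 ± 134 FPKM. Il6, another cytokine, stood at 0.0120 ± 0.0170, 0.111 ± 0.0940, 1.20 ± 0.824 and 38.0 ± 16.6 FPKM. Ifit1, an interferon-stimulated gene, stood at 1.40 ± 0.432, 1.08 ± 0.304, 3.35 ± 1.65 and 86.3 ± 33.9 FPKM.

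**Figure D2:**
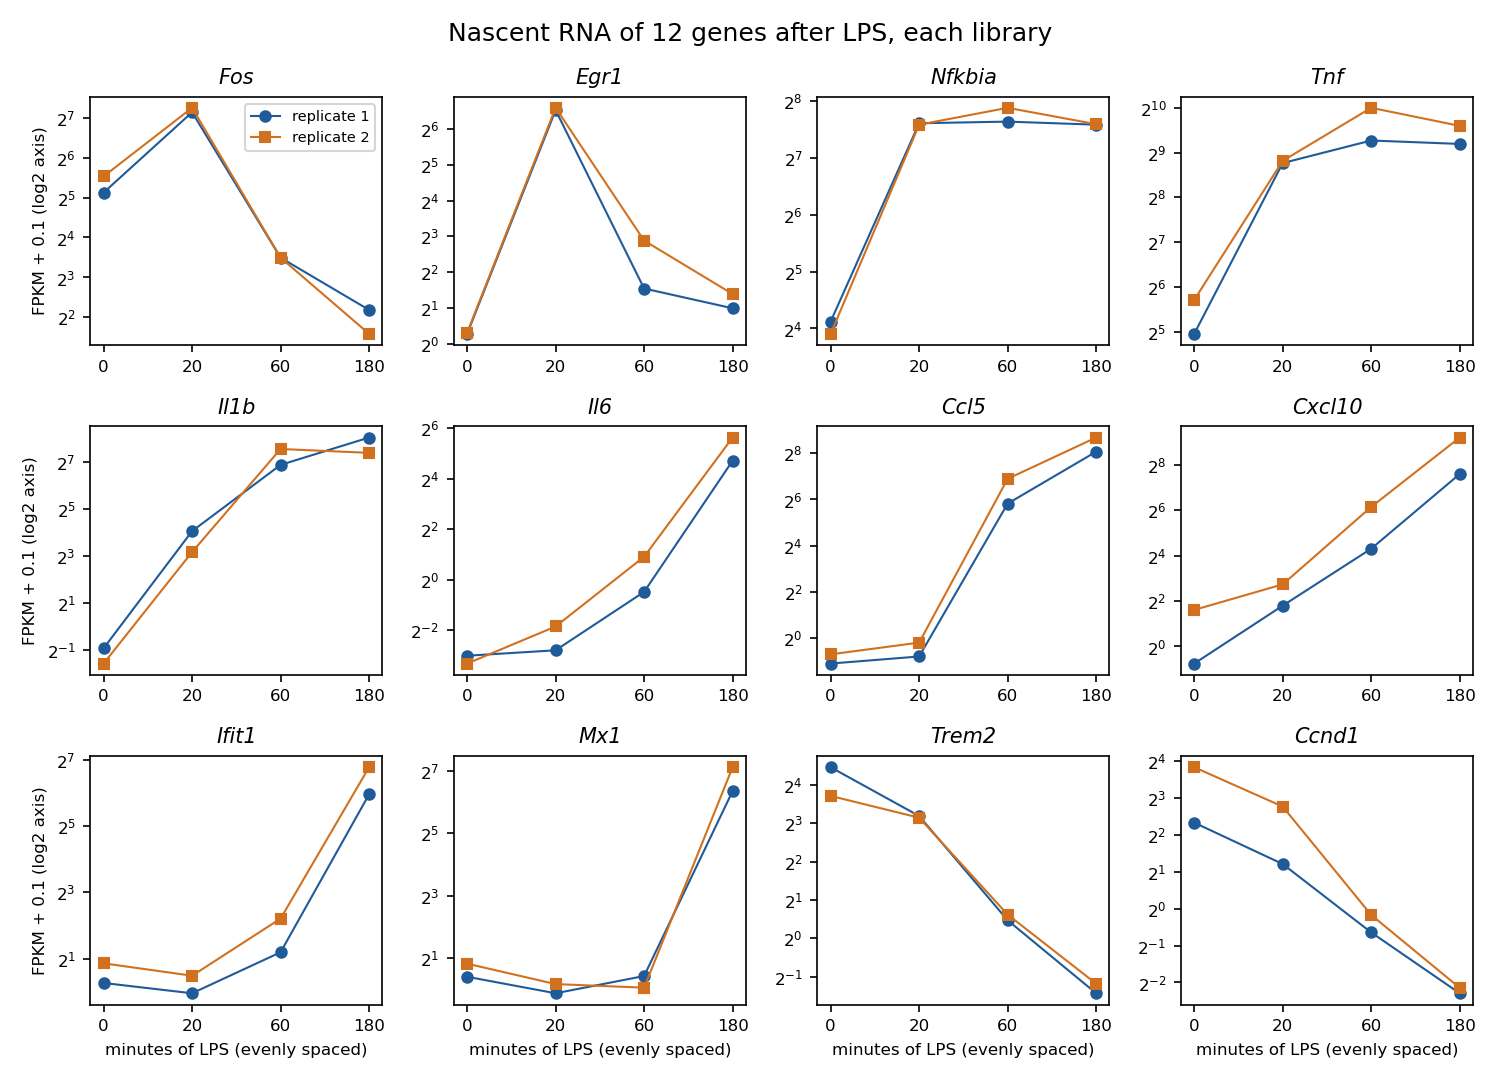
FPKM (log2 axis) of 12 genes at 0, 20, 60 and 180 min of LPS, evenly spaced, with 0.1 added, 1 point per library and 1 line per replicate number. Nfkbia went from 16.1 FPKM at 0 min to 193 FPKM at 20 min, whereas Ifit1 was at 1.40 FPKM at 0 min and 86.3 FPKM at 180 min.

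The first comparison, 20 min with 0 min, asked which genes were transcribed at a different rate shortly after LPS. Egr1, a zinc finger transcription factor of the immediate early class (mm9, chromosome 18, 35020861 to 35024610), went from 1.12 ± 0.0191 to 94.2 ± 3.02 FPKM and rose by 6.27 ± 0.46 (adjusted p = 0.0177). Genes of the NF-kB feedback loop rose in the same interval. Nfkbia, which encodes the inhibitor that holds NF-kB in the cytoplasm (mm9, chromosome 12, 56590396 to 56593634), rose by 3.58 ± 0.31, from 16.1 ± 1.71 to 193 ± 2.41 FPKM. Tnfaip3, a ubiquitin-editing enzyme that limits NF-kB signalling, rose by 3.72 ± 0.36, and Nfkbiz, a nuclear cofactor of NF-kB, rose by 3.61 ± 0.33. The cytokine genes Il1b and Tnfsf9 rose by 4.86 ± 0.48 and 4.14 ± 0.46, and the neutrophil-attracting chemokine Cxcl1 rose by 5.27 ± 0.41, reaching 52.2 ± 22.7 FPKM. Nlrp3, the sensor of an inflammasome, rose by 3.32 ± 0.37, and Sod2, the mitochondrial superoxide dismutase, rose by 2.71 ± 0.30.

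These 9 genes were all that limma called higher in the unpaired fit, and 0 were called lower, against 234 higher and 264 lower at an unadjusted p under 0.05. The paired fit called 192 higher and 57 lower, and 168 and 23 after median-ratio scaling. Voom on recovered read numbers, a choice made after seeing the data, called 45 higher and 0 lower. The median change over all genes tested was -0.20. The unpaired calls rested on all libraries, and no library was left out of the paired fit. Without any 1 of the 0, 20 or 180 min libraries limma called 0 genes, with 185 to 617 at an unadjusted p under 0.05, and without either 60 min library it called 2.

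Several genes with large values at 20 min were called in the paired fit alone. Cxcl2, a neutrophil chemokine, was at 12 ± 9.47 and 379 ± 109 FPKM (adjusted p = 0.0832 unpaired and 2.5e-04 paired). Tnf was at 41.5 and 443 FPKM (0.0607 and 4.6e-04), and Ccl4, a chemokine for monocytes, at 20.1 ± 0.371 and 91.9 ± 5.25 FPKM (0.0784 and 0.00160). Fos was at 40.4 and 146 FPKM (0.182 and 0.00618). Junb, its dimer partner, was at 23.2 ± 0.311 and 108 ± 20.9 FPKM (0.106 and 0.00257). Ptgs2, the inducible cyclooxygenase, was at 0.292 ± 0.0962 and 2.69 ± 0.545 FPKM (0.0669 and 0.00160). Socs3, an inhibitor of cytokine receptor signalling, was at 0.442 ± 0.107 and 8.43 ± 4.84 FPKM (0.0669 and 2.3e-04). The genes lowest in the paired fit included Pycard, the inflammasome adaptor, at 7.33 ± 2.87 and 1.21 ± 0.0813 FPKM (0.117 unpaired and 0.00281 paired).

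By gene list at 20 min, 1 of 25 immediate early and stress transcription factors was called higher over all genes tested, 11 adjusted over the list alone and 14 in the paired fit. Of 22 NF-kB subunits and feedback genes, 3 were called higher over all genes, 16 adjusted over the list alone and 18 in the paired fit. For 21 cytokines the counts were 2, 6 adjusted over the list alone and 6 paired. For 16 chemokines they were 1, 7 adjusted over the list alone and 9 paired. For 13 inflammatory effector enzymes they were 1, 3 adjusted over the list alone and 3 paired. No gene of 13 in costimulation and adhesion passed limma over all genes, whereas 7 were called higher adjusted over the list alone and 8 in the paired fit. Among them, Cd83, a marker of activated antigen-presenting cells, was at 1.62 ± 0.697 and 32.1 ± 19.2 FPKM, and Clec4e, a receptor for mycobacterial lipid, was at 3.48 ± 3.08 and 47.4 ± 26.3 FPKM. Of 14 MAP kinase phosphatases and mRNA decay factors, 0 passed limma over all genes, 6 were called higher adjusted over the list alone and 6 in the paired fit. Higher calls in the 7 lists, in the order given, were 1, 1, 2, 1, 0, 0 and 0 after median-ratio scaling. After quantile normalization they were 1, 5, 2, 1, 2, 3 and 1. Camera placed all 7 of these lists above the other genes, with adjusted p from 1.2e-41 for NF-kB genes to 4.1e-09 for effector enzymes. All 7 calls held with a correlation estimated per list, at adjusted p from 0.0185 to 0.0368. Camera also placed Toll-like receptor (adjusted p = 0.0121), antigen presentation (0.0184), cholesterol synthesis (0.0231), alternative activation (0.0293) and macrophage identity genes (0.0492) upward. These became adjusted p = 0.396, 0.396, 0.595, 0.155 and 0.155 with an estimated correlation, and no member of these 5 lists passed limma over all genes.

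Of 40 interferon-stimulated genes, 0 were called at 20 min in either direction by limma over all genes, with 1 higher adjusted over the list alone and 1 in the paired fit. Their median change was -0.22, their mean -0.08, and camera gave an adjusted p of 0.605 in the upward direction. Ifit1 was at 1.40 ± 0.432 and 1.08 ± 0.304 FPKM (adjusted p = 0.997). Ifnb1, the gene for interferon beta (mm9, chromosome 4, 88167929 to 88168698), was listed at 0 in all 4 libraries of 0 and 20 min. Cxcl10, an interferon-inducible chemokine, was listed at 0.494 and 2.96 FPKM at 0 min and 3.38 and 6.57 FPKM at 20 min (adjusted p = 0.967 unpaired and 0.0168 paired).

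The second comparison, 60 min with 0 min, asked the same of a later time. Il1b, the precursor of interleukin 1 beta (mm9, chromosome 2, 129190316 to 129196856), rose by 8.46 ± 0.48, from 0.328 ± 0.134 to 151 ± 49.3 FPKM (adjusted p = 0.00151). Irg1, which makes the antibacterial metabolite itaconate, rose by 7.34 ± 0.73 and reached 296 ± 122 FPKM. Ccl5, a chemokine for T cells, rose by 7.28 ± 0.47 to 87.7 ± 44.3 FPKM. Cxcl1 and Socs3 rose by 7.16 ± 0.41 and 6.63 ± 0.50. Il1a rose by 6.26 ± 0.41, Ptgs2 by 5.94 ± 0.38 and Cxcl2 by 5.94 ± 0.75. Cxcl2 was listed at 347 and 1108 FPKM in the 60 min replicates, so its level varied between them. Tnf rose by 4.31 ± 0.43, Nfkbia by 3.74 ± 0.31 and Ccl4 by 3.22 ± 0.31.

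Ifnb1, listed at 0 at 0 min, was listed at 0.959 and 2.80 FPKM in the 60 min replicates (adjusted p = 0.00696). Il6 rose by 3.38 ± 0.57 to 1.20 ± 0.824 FPKM, with an adjusted p up to 0.0677 without 0 min replicate 2. Cxcl10 rose by 4.80 ± 0.99, with an adjusted p up to 0.108 without 60 min replicate 2.

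Among genes lower at 60 min, Tifab, an inhibitor of the adaptor TIFA, fell by 4.71 ± 0.38, from 6.50 ± 2.31 to 0.152 ± 0.0919 FPKM. Gpr146, an orphan receptor, fell by 4.62 ± 0.53, and Angptl2, a secreted angiopoietin-like protein, fell by 4.09 ± 0.34. Cerk, which phosphorylates ceramide, fell by 4.02 ± 0.44, and Cnr2, a cannabinoid receptor, fell by 4.0 ± 0.28. Asph, an aspartyl hydroxylase, fell by 4.0 ± 0.30. Treml1, a receptor of the Trem family, fell by 3.97 ± 0.33. Cd200r1, an inhibitory receptor of myeloid cells, fell by 3.84 ± 0.38. Fos was below its starting level, having fallen by 1.83 ± 0.34, with an adjusted p up to 0.121 without 0 min replicate 2.

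In all, 423 genes were called higher and 734 lower at 60 min, and 976 and 2328 in the paired fit. The median change over all genes was -0.29. After median-ratio scaling, which removes that shift, 561 were called higher and 553 lower, and after quantile normalization 625 and 577. The paired fit with median-ratio scaling called 1626 and 1696. The total of 1157 was 223 without 0 min replicate 1 and 299 without 0 min replicate 2. It was 761 and 718 without 20 min replicates 1 and 2, and 403 without 60 min replicate 2. A set of 183 genes, 116 higher and 67 lower, kept the call whichever of the 8 libraries was left out.

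By gene list at 60 min, 16 of 22 NF-kB genes were called higher, 19 adjusted over the list alone, including Tnfaip3 at 4.85 ± 0.36 and Traf1, a signalling adaptor, at 4.20 ± 0.34. Camera gave an adjusted p of 1.2e-20 for this list, and the adjusted p was 0.0525 with an estimated correlation. With fry it was 7.7e-04 upward. Of 21 cytokines, 14 were called higher, 17 adjusted over the list alone, with Il12b, the shared subunit of interleukins 12 and 23, at 5.62 ± 0.41 and Tnfsf9 at 4.88 ± 0.46. Of 16 chemokines, 12 were called higher, 13 adjusted over the list alone, with Cxcl3 at 4.87 ± 0.50. Of 13 costimulation and adhesion genes, 8 were called higher, 11 adjusted over the list alone and 12 in the paired fit. They included Cd40 at 5.63 ± 0.37, Cd83 at 5.41 ± 0.55 and Icam1, an adhesion receptor for leukocytes, at 5.06 ± 0.35. Of 13 effector enzymes, 8 were called higher and 1 lower, 9 and 1 adjusted over the list alone, with Sod2 at 3.92 ± 0.30 and Ptges, a prostaglandin E synthase, at 3.54 ± 0.36. For cytokines, chemokines, effector enzymes and costimulation genes the camera calls held with an estimated correlation, at adjusted p from 0.0386 to 0.0390.

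Immediate early genes went both ways at 60 min, with 4 of 25 called higher and 2 lower, the same numbers adjusted over the list alone, and 14 and 3 in the paired fit. After median-ratio scaling 7 were called higher and 1 lower. Camera gave this list an adjusted p of 0.000692 upward, which was an adjusted p = 0.446 with an estimated correlation. Egr1 remained above its starting level by 1.92 ± 0.46, with an adjusted p up to 0.162 without 0 min replicate 1, and Junb by 1.98 ± 0.34, with an adjusted p up to 0.0858 without 0 min replicate 1. MAP kinase phosphatases and decay factors also went both ways, with 3 of 14 higher and 3 lower, 4 and 3 adjusted over the list alone, and 7 and 3 in the paired fit. The camera call for it, at an adjusted p of 0.0482, was an adjusted p = 0.446 with an estimated correlation. In this list Dusp5, a nuclear ERK phosphatase, rose by 3.58 ± 0.32, while Dusp6, the cytoplasmic one, fell by 2.94 ± 0.33. Zfp36l2, an RNA-binding protein that promotes mRNA decay, fell by 3.58 ± 0.39.

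In the LPS receptor and Toll-like receptor list, 6 of 28 genes were called higher and 3 lower at 60 min, 7 and 3 adjusted over the list alone, and 11 and 5 in the paired fit. Camera gave an adjusted p of 0.00756 upward, and an adjusted p = 0.446 with an estimated correlation. Ikbke, a kinase that activates interferon regulatory factors, rose by 2.74 ± 0.32. Tlr2, the receptor for bacterial lipoproteins, rose by 3.56 ± 0.59 (up to 0.0671 without 0 min replicate 2), and Cd14, the coreceptor for LPS, by 2.33 ± 0.41 (up to 0.0845 without 0 min replicate 2). Tlr4 itself fell by 2.13 ± 0.32 (up to 0.0651 without 0 min replicate 2), from 5.33 ± 0.373 to 1.16 ± 0.281 FPKM. These last values in parentheses are the highest adjusted p with 1 library left out.

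Of 40 interferon-stimulated genes, 7 were called higher and 0 lower by limma at 60 min, the same numbers adjusted over the list alone, and 11 and 7 in the paired fit. They included the interferon-inducible GTPase genes Gbp5 at 5.17 ± 0.46 and Gbp2 at 3.41 ± 0.33. The transcription factor Irf1 rose by 3.42 ± 0.39 and Ifi205, of the interferon-inducible p200 family, by 2.50 ± 0.31. The list's median change was -0.17 and turned to 0.12 after median-ratio scaling and 0.05 after quantile normalization, its mean was 0.42, and camera gave an adjusted p of 0.0287 upward. That became an adjusted p = 0.648 with an estimated correlation. Mx1, an antiviral GTPase, was at 1.44 ± 0.315 and 1.09 ± 0.216 FPKM (adjusted p = 0.583). Of 16 antigen presentation genes, Tapbp, the chaperone tapasin, was called, having risen by 1.48 ± 0.31 with an adjusted p up to 0.162 without 0 min replicate 1. The paired fit called 7 of the 16 higher, 1 passed adjusted over the list alone, and camera's adjusted p of 0.00736 upward was an adjusted p = 0.446 with an estimated correlation.

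Macrophage identity genes were called both ways at 60 min, with 3 of 26 higher and 7 lower, 4 and 12 adjusted over the list alone, and 6 and 14 in the paired fit. Trem2, a receptor for lipids on tissue macrophages, fell by 3.53 ± 0.33, and Fcgr1, the high-affinity receptor for immunoglobulin G, fell by 3.54 ± 0.43. Tfec, a transcription factor of the MiT family, rose by 3.47 ± 0.42. Camera did not call this list, with an adjusted p of 0.417 downward, whereas fry gave an adjusted p of 0.00292 downward. Fry, here and for the lists below, used the deposited values. The median of all genes was -0.29 there, so fry may also count that shift. The median of the list was -0.96 as deposited. After median-ratio scaling it was -0.63, with 2 called higher and 5 lower, and after quantile normalization -1.42, with 2 and 10. Of 8 genes of alternative activation, 1 was called higher and 3 lower, 1 and 5 adjusted over the list alone, and 3 and 5 in the paired fit. For this list camera gave an adjusted p of 0.368 and fry 0.00255, both downward. Stab1, a scavenger receptor, fell by 2.29 ± 0.26, and Pparg, a lipid-sensing nuclear receptor, fell by 2.02 ± 0.37 with an adjusted p up to 0.106 without 0 min replicate 2. Of 13 liver X receptor targets, 3 were called lower, 3 adjusted over the list alone and 6 in the paired fit, which also called 2 higher. One was Npc1, which moves cholesterol out of lysosomes and fell by 2.16 ± 0.34 (up to 0.0741 without 0 min replicate 1). Of 20 cell cycle genes, 3 were called lower, 8 lower and 1 higher adjusted over the list alone, and 14 lower and 1 higher in the paired fit. Ccnd1, cyclin D1, fell by 3.49 ± 0.64 with an adjusted p up to 0.0769 without 0 min replicate 2. Camera gave the cell cycle list an adjusted p of 0.00258 downward, and an adjusted p = 0.446 with an estimated correlation. With fry it was 0.0324 downward.

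The third comparison, 180 min with 0 min, covered the longest interval. Ccl5 (mm9, chromosome 11, 83339281 to 83344020) had the largest rise by the naming rule, at 9.30 ± 0.47, from 0.432 ± 0.104 to 341 ± 101 FPKM (adjusted p = 3.6e-04). Il6 rose by 8.34 ± 0.57, and the interleukin 1 genes Il1b and Il1a rose by 8.96 ± 0.48 and 7.81 ± 0.41. Ptgs2 rose by 8.21 ± 0.38 and Edn1, the vasoconstrictor endothelin 1, by 7.79 ± 0.43. Gbp5 rose by 8.00 ± 0.46 and Cxcl10 by 7.97 ± 0.99, the latter to 193 and 590.2 FPKM in the 180 min replicates. Tnf, Nfkbia and Ccl4 were still above 0 min, by 4.07 ± 0.43, 3.57 ± 0.31 and 4.75 ± 0.31. Ifnb1 was listed at 0.850 and 2.12 FPKM (adjusted p = 0.00430).

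Among genes lower at 180 min, Slc37a2, a sugar phosphate transporter of macrophages, fell by 5.57 ± 0.34, from 9.46 ± 0.363 to 0.109 ± 0.0806 FPKM. Trem2 (mm9, chromosome 17, 48485726 to 48491601) fell by 5.38 ± 0.33, from 17.4 ± 6.25 to 0.307 ± 0.0495 FPKM. Ccnd1 fell by 5.31 ± 0.64 and Cerk by 4.74 ± 0.44. Cd300lb, an activating receptor of myeloid cells, fell by 5.02 ± 0.38. Lrp1, a receptor for endocytosis of apolipoproteins, fell by 4.62 ± 0.52. Susd3, a membrane protein, fell by 4.59 ± 0.54. Dnmt3aos, annotated antisense to Dnmt3a, fell by 5.10 ± 0.43, a value that depends on how reads on the opposite strand were counted, which is not given in the sources used here. Fos fell by 3.44 ± 0.34.

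In all, 745 genes were called higher and 1951 lower at 180 min, and 1184 and 4302 in the paired fit. The median change over all genes was -0.69. After median-ratio scaling 1124 were called higher and 1052 lower, and after quantile normalization 995 and 960. The paired fit with median-ratio scaling called 2176 and 2149. The total of 2696 was 1188 without 0 min replicate 1, 1122 without 0 min replicate 2 and 1305 without 180 min replicate 2. A set of 823 genes, 311 higher and 512 lower, kept the call whichever library was left out.

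Interferon-stimulated genes rose as a group by 180 min, with 38 of 40 called higher and 0 lower, 39 adjusted over the list alone and 40 in the paired fit. Rsad2, the antiviral enzyme viperin, rose by 6.36 ± 0.61, Gbp2 by 6.24 ± 0.33, Ifi205 by 6.25 ± 0.31 and Ifit1 by 5.82 ± 0.49. The median change of the list was 3.85, and camera gave an adjusted p of 2.2e-41, which held at 0.0412 with an estimated correlation. The genes not called were Irf9, at 7.72 ± 1.86 and 13.5 ± 3.48 FPKM, and Rtp4, at 17.1 ± 9.92 and 57.6 ± 22.7 FPKM (adjusted p = 0.130 and 0.0940). In the paired fit these were 0.00863 and 2.0e-04.

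Of 21 cytokines, 18 were called higher and 1 lower at 180 min, with the same numbers adjusted over the list alone, and 18 and 0 after median-ratio scaling or quantile normalization. Of 16 chemokines, 15 were called higher and 1 lower, again with the same numbers adjusted over the list alone, 15 and 0 after median-ratio scaling and 13 and 1 after quantile normalization. Cxcl3 rose by 7.64 ± 0.50. Of 22 NF-kB genes, 17 were called higher, 18 adjusted over the list alone and 20 in the paired fit, including Socs3 at 7.39 ± 0.50 and Tnfaip3 at 5.08 ± 0.36. Of 13 effector enzymes, 10 were called higher, 11 adjusted over the list alone and 12 in the paired fit. Among them Nos2, the inducible nitric oxide synthase, rose by 7.05 ± 0.37, Irg1 by 7.75 ± 0.73 and Slc7a2, an arginine transporter, by 5.54 ± 0.30. Of 13 costimulation and adhesion genes, 9 were called higher, 9 adjusted over the list alone and 11 in the paired fit, with Cd40 at 6.68 ± 0.37 and Clec4e at 5.30 ± 0.85. The camera calls for cytokines, chemokines, effector enzymes and costimulation held with an estimated correlation, at adjusted p from 0.0197 to 0.0350. For NF-kB genes camera's adjusted p of 5.4e-18 was an adjusted p = 0.0578 with an estimated correlation.

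Of 16 antigen presentation genes, 6 were called higher and 0 lower by limma at 180 min, 7 adjusted over the list alone and 13 in the paired fit. Nlrc5, the transactivator of class I genes, rose by 2.79 ± 0.33 and Tapbp by 2.39 ± 0.31. Tap1, a subunit of the peptide transporter, rose by 2.98 ± 0.54, with an adjusted p up to 0.0515 without 180 min replicate 2. The list's camera adjusted p of 6.9e-08 was an adjusted p = 0.101 with an estimated correlation. In the Toll-like receptor list, 10 of 28 genes were called higher and 3 lower, 12 and 6 adjusted over the list alone, and 15 and 6 in the paired fit. These were 15 and 1 after median-ratio scaling and 12 and 1 after quantile normalization. Ikbke rose by 1.99 ± 0.32 and Tlr13, a sensor of bacterial ribosomal RNA, fell by 2.12 ± 0.28. For this list the camera adjusted p of 8.3e-05 upward was an adjusted p = 0.249 with an estimated correlation.

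Of 25 immediate early genes at 180 min, 3 were called higher and 3 lower, the same adjusted over the list alone, and 8 and 5 in the paired fit. The numbers were 5 and 1 after median-ratio scaling and 3 and 3 after quantile normalization. With camera, the adjusted p of 0.0131 upward was an adjusted p = 0.423 with an estimated correlation. Myc, a growth-promoting transcription factor, fell by 1.44 ± 0.40, with an adjusted p up to 0.168 without 180 min replicate 2, and Ier3, a stress-inducible survival gene, rose by 2.42 ± 0.58, with an adjusted p up to 0.106 without 0 min replicate 2. Of 14 MAP kinase phosphatases and decay factors, 3 were called higher and 4 lower, the same adjusted over the list alone, and 4 and 6 in the paired fit. Dusp16, a phosphatase of JNK, rose by 2.90 ± 0.31, while Zfp36l2 fell by 4.29 ± 0.39 and Zfp36l1, its relative, by 3.03 ± 0.33. The median of this list was -0.47, turned to 0.23 after median-ratio scaling and was -0.13 after quantile normalization, with a camera adjusted p of 0.853 upward.

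Of 20 cell cycle genes, 15 were called lower and 0 higher by limma at 180 min, 16 adjusted over the list alone and 18 in the paired fit, which called 1 higher. After median-ratio scaling 11 were called lower and 1 higher, and after quantile normalization 8 and 1. E2f2, a transcription factor of S phase entry, fell by 4.02 ± 0.30, and E2f1 by 3.13 ± 0.68, with an adjusted p up to 0.0759 without 180 min replicate 2. The median of the list was -2.53, and -1.86 and -1.62 after the same scalings. By camera, the adjusted p of 0.000556 downward was an adjusted p = 0.309 with an estimated correlation. Mki67, a marker of proliferation, was not called, at 2.03 ± 0.788 and 4.17 ± 1.42 FPKM (adjusted p = 0.125 unpaired and 0.0312 paired).

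Of 26 macrophage identity genes, 2 were called higher and 8 lower at 180 min, the same adjusted over the list alone, and 9 and 13 in the paired fit. Fcgr2b, the inhibitory Fc receptor, rose by 4.7 ± 0.38 and Tfec by 3.55 ± 0.42, whereas Cd36, a scavenger receptor, fell by 4.06 ± 0.58. The median of the list was -0.62, turned to 0.11 after median-ratio scaling and was -0.76 after quantile normalization, and camera gave an adjusted p of 0.646 upward. All 8 alternative activation genes tested were called, 2 higher and 6 lower, the same adjusted over the list alone and in the paired fit. Those lower were 5 after median-ratio scaling and 4 after quantile normalization. Stab1 fell by 3.84 ± 0.26, Pparg by 3.82 ± 0.37 and Mrc1, the mannose receptor, by 2.68 ± 0.45. Camera did not call the list against the other genes, at an adjusted p of 0.225. Of 13 liver X receptor targets and lipid efflux genes, 1 was called higher and 5 lower, the same adjusted over the list alone, and 1 and 10 in the paired fit. Quantile normalization left 0 higher and 3 lower. Scd2, a fatty acid desaturase, fell by 2.85 ± 0.44 and Npc1 by 2.39 ± 0.34, and camera's adjusted p for the list was 0.451 downward.

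Of 18 glycolysis genes, 3 were called higher and 0 lower by limma at 180 min, 1 adjusted over the list alone, and 6 higher and 3 lower in the paired fit. Pfkfb3, a regulator of phosphofructokinase, rose by 2.95 ± 0.43. Their camera adjusted p of 0.00909 upward was an adjusted p = 0.339 with an estimated correlation. Of 18 genes of the transcription elongation machinery, 1 was called higher and 5 lower, the same adjusted over the list alone, and 1 and 8 in the paired fit. These became 1 and 1 after median-ratio scaling, and 1 and 0 by limma after quantile normalization. Aff1, a scaffold of the super elongation complex, rose by 1.92 ± 0.36 (up to 0.0666 without 0 min replicate 2), and Polr2a, the largest subunit of RNA polymerase II, fell by 2.06 ± 0.39 (up to 0.0613 without 0 min replicate 2). The values in parentheses are the highest adjusted p with 1 library left out. The median of this list was -0.50, turned to 0.21 after median-ratio scaling and was -0.01 after quantile normalization, with a camera adjusted p of 0.958 upward. Of 21 cholesterol synthesis genes, 2 were called lower, 0 by limma adjusted over the list alone, and 2 higher and 6 lower in the paired fit. The direction turned after median-ratio scaling, with 2 called higher and 0 lower, and limma called 0 after quantile normalization. Its median was -0.17, turned to 0.50 after median-ratio scaling and to 0.16 after quantile normalization, and had a camera adjusted p of 0.451 upward. At 60 min 0 of its 21 members were called, and a camera adjusted p of 0.0188 upward was an adjusted p = 0.577 with an estimated correlation. Of 16 housekeeping genes, 3 were called lower, 3 adjusted over the list alone, and 3 higher and 9 lower in the paired fit. After median-ratio scaling 1 was called higher and 2 lower, and after quantile normalization 1 lower. Gusb, the lysosomal glucuronidase, fell by 2.75 ± 0.41, and Actb, cytoplasmic actin, was at 47.4 ± 11.6 and 86.8 ± 3.51 FPKM (adjusted p = 0.143 unpaired and 0.0164 paired). The housekeeping median was -0.72, near the shift of all genes, and -0.05 and -0.26 after these scalings, with a camera adjusted p of 0.958 upward.

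**Figure D3:**
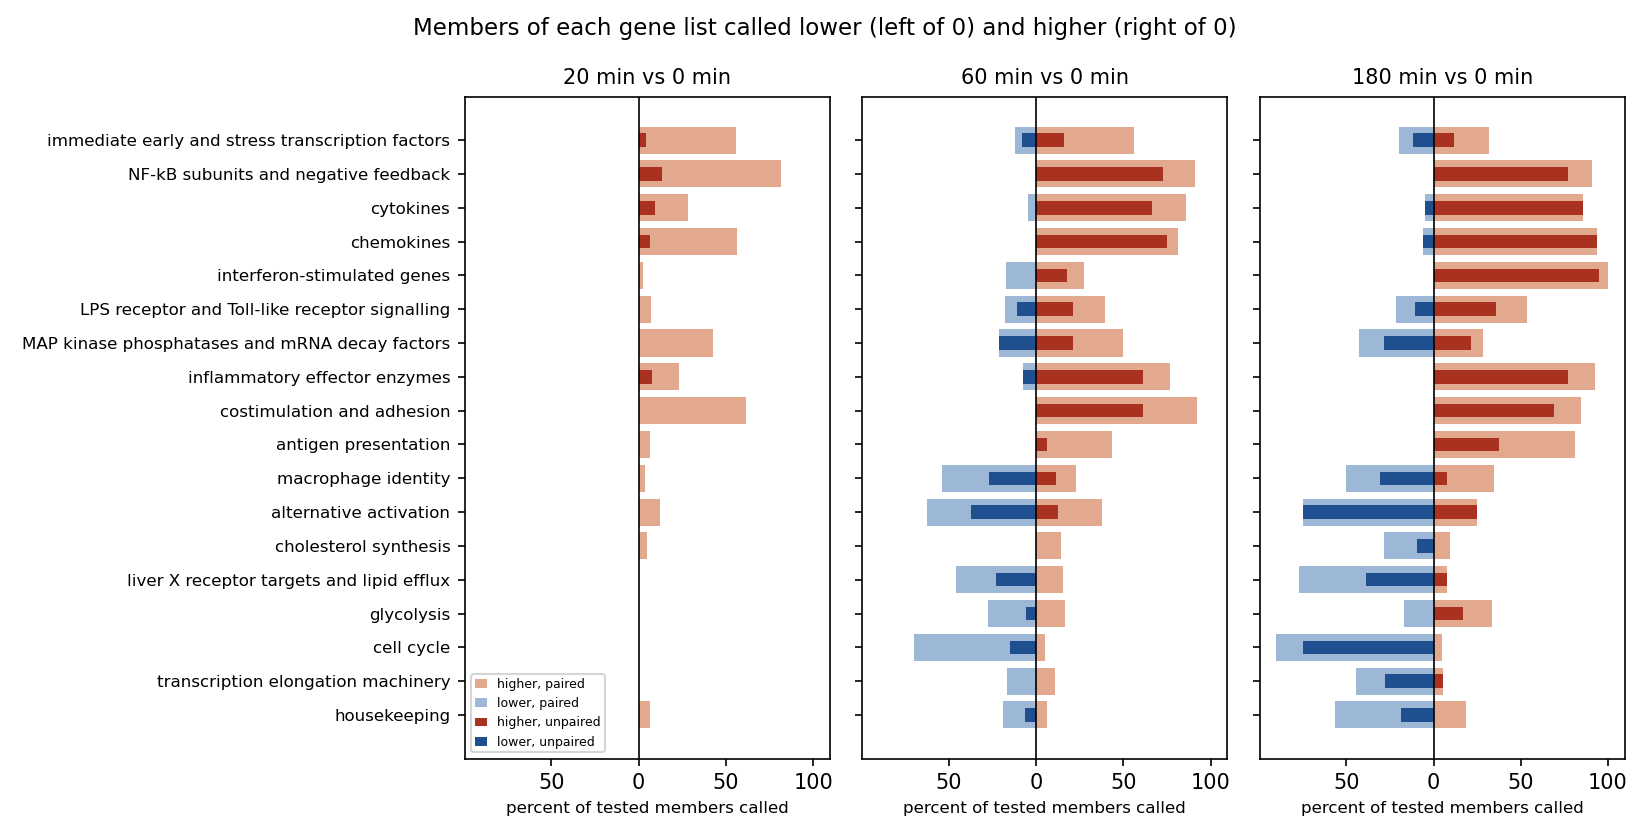
Percent of the tested members of each gene list called lower (left of 0) and higher (right of 0) by limma against 0 min, with narrow dark bars for the unpaired fit and wide light bars for the paired fit. At 180 min 38 of 40 interferon-stimulated genes were called higher in the unpaired fit and 40 in the paired fit.

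Comparing 60 min with 20 min gave the changes between the early times. Ccl5 rose by 6.87 ± 0.47, from 0.615 ± 0.208 to 87.7 ± 44.3 FPKM. The cytokine genes Il12b and Csf2 rose by 5.39 ± 0.41 and 4.68 ± 0.83. Il1a and Il27, a cytokine of the interleukin 12 family, rose by 4.63 ± 0.41 and 4.43 ± 0.50, and Irg1 rose by 4.25 ± 0.73. Nfkb1, the gene for the p105 precursor, rose by 2.46 ± 0.31. Of the immediate early genes, Egr1 fell by 4.35 ± 0.46, Fos by 3.69 ± 0.34 and Jun by 2.83 ± 0.37. Treml1, Asph and Gpr146 fell by 4.23 ± 0.33, 4.0 ± 0.30 and 3.80 ± 0.53. In all, 190 genes were called higher and 289 lower, and 775 and 1219 in the paired fit. The total of 479 was 0 without either 20 min library, where limma gave 1064 and 920 genes at an unadjusted p under 0.05. It was 164 without either 0 min library, and 80 and 15 without 60 min replicates 1 and 2. Of the 479 genes, 0 kept the call whichever library was left out. With only the 20 and 60 min libraries in the fit limma called 0, with 1389 at an unadjusted p under 0.05. Voom called 808.

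By list between 20 and 60 min, 8 of 21 cytokines, 5 of 16 chemokines, 3 of 22 NF-kB genes, 4 of 13 effector enzymes and 3 of 13 costimulation genes were called higher. These were 11, 7, 8, 9 and 4 adjusted over the list alone, and 14, 10, 13, 9 and 7 in the paired fit. After quantile normalization 9, 3, 3, 5 and 3 were called higher. In the same lists 1 effector enzyme was called lower over all genes, adjusted over the list alone and in the paired fit, which also called 1 cytokine and 1 NF-kB gene lower. Camera called these 5 lists at adjusted p from 1.8e-10 to 3.4e-05, and with an estimated correlation the adjusted p ran from 0.121 to 0.249. Of 25 immediate early genes 3 were called lower, 4 adjusted over the list alone, and 9 lower and 2 higher in the paired fit, with a camera adjusted p of 0.0286 downward and an adjusted p = 0.589 with an estimated correlation. Of 26 macrophage identity genes 5 were called lower and 2 higher, 9 and 2 adjusted over the list alone, and 15 and 5 in the paired fit. The camera adjusted p for that list was 0.0267 downward, and adjusted p = 0.179 with an estimated correlation. Cell cycle genes (1 of 20 lower, 7 adjusted over the list alone, 11 paired) had a camera adjusted p of 4.7e-05 downward, and adjusted p = 0.266 with an estimated correlation. Interferon-stimulated genes (5 of 40 higher, 6 adjusted over the list alone, 12 higher and 1 lower paired) had 0.0116 upward, and adjusted p = 0.589 with an estimated correlation.

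Comparing 180 min with 60 min gave the changes between the late times. Mx1 (mm9, chromosome 16, 97668642 to 97684513) rose by 6.50 ± 0.37, from 1.09 ± 0.216 to 110.2 ± 40.4 FPKM (adjusted p = 0.00279). Its relative Mx2 rose by 5.57 ± 0.37, and Cmpk2, a mitochondrial nucleotide kinase, rose by 5.71 ± 0.43. Nos2 and Edn1 rose by 5.38 ± 0.37 and 5.02 ± 0.43, and Fcgr1 rose by 4.56 ± 0.43. Lmna, which encodes lamins A and C, fell by 4.13 ± 0.32, Adam8, a membrane protease, by 3.95 ± 0.33 and Dusp5 by 3.73 ± 0.32. These 9 genes kept their calls whichever library was left out. Plau, the urokinase plasminogen activator, fell by 4.16 ± 0.55 (up to 0.0964 without 180 min replicate 2), and Igf1, a growth factor, fell by 4.08 ± 0.60 (up to 0.123 without 180 min replicate 2). Il6 rose by 4.96 ± 0.57 (up to 0.0778 without 180 min replicate 2), and Ifit2, another antiviral gene, rose by 5.62 ± 0.89 (up to 0.135 without 180 min replicate 2). Values in parentheses are the highest adjusted p with 1 library left out.

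In all, 340 genes were called higher and 327 lower from 60 to 180 min, and 872 and 2247 in the paired fit. The median change was -0.39. After median-ratio scaling 424 were called higher and 241 lower, and after quantile normalization 300 and 173. The paired fit with median-ratio scaling called 1251 and 1120. The total of 667 was 59 without 180 min replicate 2 and 1014 without 180 min replicate 1. It was 304 and 126 without 60 min replicates 1 and 2, 373 and 360 without 0 min replicates 1 and 2, and 326 and 307 without 20 min replicates 1 and 2. Of the 667 genes, 55 kept the call whichever library was left out, 41 higher and 14 lower. Of 40 interferon-stimulated genes, 35 were called higher, 38 adjusted over the list alone and 39 in the paired fit, with a median change of 3.32. Camera's adjusted p of 8.0e-52 was an adjusted p = 0.0689 with an estimated correlation. Of 13 effector enzymes, 5 were called higher, 9 adjusted over the list alone, and 9 higher and 1 lower in the paired fit. That list's camera adjusted p of 1.1e-09 was an adjusted p = 0.0501 with an estimated correlation. Of 21 cytokines, 7 were called higher and 1 lower, 9 and 2 adjusted over the list alone, and 9 and 3 in the paired fit, with a camera adjusted p of 1.7e-05 and an adjusted p = 0.298 with an estimated correlation. Antigen presentation (3 of 16 higher, 5 adjusted over the list alone, 8 higher and 1 lower paired) and glycolysis genes (3 of 18 higher, 4 adjusted over the list alone, 5 paired) had camera adjusted p of 8.4e-05 and 0.00132 upward. Both became adjusted p = 0.298 with an estimated correlation. Tnf, Il1b and Nfkbia were not called in this interval, at adjusted p of 0.760, 0.549 and 0.762.

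**Figure D4:**
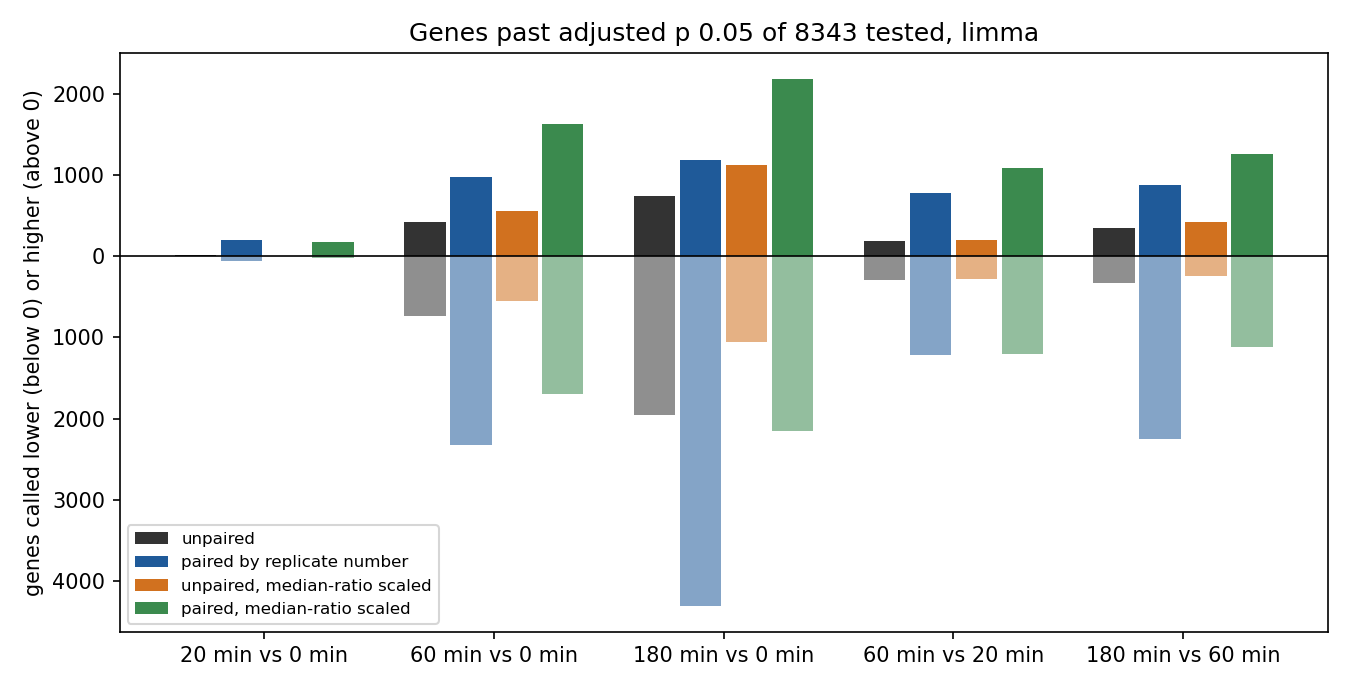
Number of genes called higher (above 0) and lower (below 0) by limma in each comparison, in the unpaired and paired fits and in both fits after median-ratio scaling. Counts in the unpaired fit ran from 9 higher and 0 lower at 20 min to 745 higher and 1951 lower at 180 min.

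Calls against 0 min overlapped between times. All 9 genes higher at 20 min were also called higher at 60 min, against 0.456 expected from independent lists, and 8 of them were called higher at 180 min, against 0.804. Between 60 and 180 min, 324 genes were called higher at both, against 37.8 expected, and 611 lower at both, against 171.6. The comparisons shared the same 0 min libraries and the same estimate of spread per gene, so the lists were not independent. With different 0 min libraries, as below, the 20, 60 and 180 min libraries and the spread estimated from them stayed shared. In 20 simulations without any effect the overlaps were 0, but the unpaired fit made 0 false calls on simulated data, so that value says nothing of overlap due to shared controls. With a different 0 min library in each comparison, a choice made after seeing the data, 101 and 125 genes were higher at both 60 and 180 min in the 2 arrangements, against 6.93 and 9.08 expected. Lower at both were 66 and 102, against 6.91 and 11.6. At 20 min limma called 0 genes with 1 control, so its overlaps could not be checked in this way, and part of them may come from the shared controls.

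Markers of other blood and tissue cells were low in these cultures. Of 14 markers of T and NK cells, 8 of mast cells and basophils, 11 of the erythroid and megakaryocyte lineages and 12 of stroma and endothelium, 0 passed the filter on FPKM. For B cells and dendritic cells 1 marker each passed, and neither was called at any time. Of 13 granulocyte markers in the file, 3 passed. Csf3r, the receptor for granulocyte colony-stimulating factor, which macrophages also express, rose at 180 min by 1.44 ± 0.35, with an adjusted p up to 0.135 without 0 min replicate 2. S100a8 and S100a9, the calprotectin genes, were not called at 180 min (adjusted p = 0.249 and 0.795). Camera's adjusted p for these 3 genes at 180 min was 0.0475, and an adjusted p = 0.222 with an estimated correlation.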

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

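The tests of the shallower replicate, of reads outside genes and of incomplete transcription as the whole cause were chosen after results had been seen. The check for long genes catching up later also had no prediction written first. All other tests in this part had their predictions written first.

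In 9 named genes the paired fit called opposite directions against 0 min at successive times, and the direct comparison of those times was called in both fits. The unpaired fit called none of them at both times against 0 min. Over all genes tested, such opposite calls at 60 and 180 min were made for 1 gene higher first and 9 lower first in the unpaired fit. In the paired fit these were 53 and 76. Fos was 1.86 above 0 min at 20 min and -1.83 at 60 min on the log2 scale, with a direct change of -3.69, and Jun was at 1.40 and -1.43, with -2.83. From 60 to 180 min the direct changes were 4.56 for Fcgr1, -3.32 for Folr2, 1.60 for Hk1, 5.62 for Ifit2, -2.48 for Myc, 3.14 for Tlr3 and -2.30 for Traf3. Against 0 min Fcgr1 was at -3.54 at 60 min and 1.02 at 180 min, Folr2 at 1.05 and -2.27, Hk1 at -0.88 and 0.72, and Ifit2 at -0.87 and 4.75. Myc was at 1.04 and -1.44, Tlr3 at -1.17 and 1.97, and Traf3 at 0.97 and -1.32. Only the direct call of Fcgr1 held without each library in turn, with a highest adjusted p of 0.0413. With median-ratio scaling and the block, the 60 min decreases of Hk1, Ifit2 and Tlr3 were not called (adjusted p = 0.139, 0.140 and 0.117).

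The median of all genes was lower at 180 min than at 0 min, by -0.51 in replicate 1 and -0.85 in replicate 2. Genes called higher took 3.78% of reads at 0 min and 20.5% at 180 min in replicate 1, and 3.93% and 23.2% in replicate 2. That share, spread over all other reads, would move the other genes by a mean of -0.299, while the summed reads of the other tested genes changed by -0.45 and -0.63, so it may account for part or most of the shift and the test could not tell. Low depth did not account for it, since the deeper replicate gave -0.509. The share of reads in genes changed by at most 1.13 percentage points, which by its prediction spoke against reads moving outside genes. That share includes the genes called higher, whose reads grew. It therefore cannot exclude that reads outside genes gained relative to the other genes. No biological explanation was tested, and FPKM without an added standard cannot separate a lower output of all genes from a change of shares.

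Among 423 genes called higher at 60 min, longer genes had smaller changes at 20 min (Spearman rho across genes = -0.422, permutation p = 1e-05, the smallest possible with 1e+05 permutations), whereas over all genes tested rho was 0.281. In the induced genes this met the prediction for polymerases that had not reached the ends of long genes by 20 min. The genes were chosen by a rise over the same 0 min libraries, so their selection may play a part. Without 36 genes called higher from 60 to 180 min, a later class, rho was -0.453, so those genes did not account for it. Genes that first rose between 20 and 60 min stayed in, so a later class of that kind was not tested. With mean FPKM held fixed rho was -0.318, so level did not account for all of it. Whether incomplete transcription was the whole cause could not be told. The rho of -0.350 with the change at 60 min was taken on genes chosen by that change. If long genes caught up later, rho with the change from 20 to 60 min would be positive. It was 0.0774, and -0.0923 from 60 to 180 min. Median changes in genes of 0.769 to 14.0, 14.1 to 43.2 and 43.3 to 400.4 kb were 1.35, 0.61 and 0.33 at 20 min and 2.94, 2.06 and 2.13 at 60 min.

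Neighbouring genes within 100 kb changed together at 180 min, with a rho of 0.276 over 4939 pairs after pairs sharing the first 3 letters of their symbols were left out, so tandem families did not account for it. For 1980 pairs over 20 kb apart rho was 0.185, above the highest of 1000 permuted values (0.0730, permutation p = 0.001), so transcription running past gene ends at short range did not account for all of it. With length and mean FPKM regressed out it was 0.174. Replicates 1 and 2 gave 0.183 and 0.173 over 20 kb. No biological explanation was tested.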

How the results depend on the processing

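With 2 libraries per group, counts of calls moved with most settings, while no named gene called in either setting reversed its direction. Some values not called changed sign, such as Tnf and Nfkbia from 60 to 180 min, at -0.24 and -0.17 as deposited and 0.18 and 0.24 with median-ratio scaling. Genes called at 20 min, 9 as reported, were 0 with no filter, 21 with a filter of 1 FPKM, 5 with median-ratio scaling, 22 with quantile normalization, 19 with no variance trend, 0 with only the 2 groups in the fit and 45 with voom. With no filter the count at 60 min was 1971 and at 180 min 4387, and replicate agreement was 0.948. A filter of 1 FPKM, which tested fewer genes, gave 720 at 60 min, 1615 at 180 min, 301 from 20 to 60 min and 1349 in the F-test. The replicate block gave 249, 3304, 5486, 1994 and 3119 in the comparisons as ordered in the text, and 5516 in the F-test. With median-ratio scaling as well, these were 191, 3322, 4325, 2285, 2371 and 4751. Only the 2 groups in the fit, and so fewer samples, gave 394 at 60 min, 0 from 20 to 60 min and 137 from 60 to 180 min, and voom gave 808 from 20 to 60 min. Leaving out each library gave 0 to 2, 223 to 1245, 1122 to 3075, 0 to 411, 59 to 1014 and, in the F-test, 997 to 2122, where the lone sample was assumed to vary like the other groups. Of 54 camera calls, 16 were left with the correlation estimated per list, which was done without the block. Camera made 54 calls with the block, 50 with median-ratio scaling, 51 with a pseudocount of 1 and 43 with quantile normalization. Fry made 41. Apart from fewer genes or samples, the cause was not tested.

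Of 414 values of named genes, 258 were called. The block lost 0 and added 79 calls, and changed no other call. Median-ratio scaling lost 30 and added 6, quantile normalization 27 and 6, voom 5 and 22, only the 2 groups 119 and 0, and leaving out each library lost 42 to 106. Replicate 2 was shallower, and 1 read in a gene of median length was worth up to 0.00835 FPKM there. Whether depth limited the calls of low genes was not tested.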

Other observations

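Genes called at 20 min in the paired fit had a lower median length than all tested genes, in both directions. The 57 lower genes had a median length of 3.775 kb and the 192 higher genes 9.879 kb, against 16.2 kb. For the lower genes the permutation p was 1e-05, a test chosen after results had been seen and not made for the higher ones. After median-ratio scaling the paired fit called 23 lower, whose lengths were not analysed. Pycard, the inflammasome adaptor, was at 7.33 ± 2.87 and 1.21 ± 0.0813 FPKM at 0 and 20 min. Lpar5, a receptor for lysophosphatidic acid, was at 2.20 ± 0.462 and 0.578 ± 0.136 FPKM, and Cdk5, a kinase best known in neurons, at 2.33 ± 0.810 and 0.694 ± 0.190 FPKM (paired adjusted p = 0.0381 and 0.0288). None passed the unpaired fit (adjusted p = 0.117, 0.423 and 0.312).

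Some highly transcribed genes differed between replicate numbers. Neat1, a nuclear noncoding RNA, was listed at 244 and 112 FPKM at 0 min in replicates 1 and 2, and at 99.7 and 94.6 FPKM at 180 min. Fth1, ferritin heavy chain, was listed at 152 and 68.5 FPKM at 0 min and 329 and 218 FPKM at 180 min.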
